A study of Mus musculus with 8 samples.

How the data were processed

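RNA was measured in 8 libraries of C57BL/6 mouse ASCs, 4 groups of 2. Per the labels, the cells came from the inguinal fat of male mice aged 8 weeks, were used at passage 4, and were collected 4 h after LPS at 100 ng/ml or dsDNA at 400 ng/ml. The labels give no time for the untreated and Lipofectamine groups, and they give neither the sequence nor the origin of the dsDNA. RNA was taken with Trizol and made into libraries with an unstranded Illumina TruSeq kit.

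The authors deposited 1 table of raw counts per gene symbol for all libraries. The processing notes in the labels name FastQC, cutadapt, STAR and HTSeq and the assembly mm10, with versions not given in the sources used here, nor the annotation, the strand setting and the handling of reads that map to several places. The values were checked to be whole numbers. The authors also deposited tables for LPS and dsDNA, each against its control, with a log2 fold change, a p-value and an FDR per gene. The labels name DESeq2 without a version, and how that model was fitted is not given in the sources used here. The log2 fold changes and p-values in these tables were used only to count shared genes.

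The table held 24421 symbols, 5787 of them without a count in any library. Low counts were removed by filterByExpr with the groups as design, which left 14072 genes. Libraries were scaled by TMM (factors 0.890 to 1.08), and CPM uses that scaling. A quasi-likelihood model with 1 term per group was fitted to all 8 libraries together with edgeR 4.0.16 (common dispersion 0.00286, a biological coefficient of variation of 5.35%, 4 residual and 15.6 prior degrees of freedom, prior count 0.125). Contrasts were LPS minus untreated, dsDNA minus Lipofectamine, Lipofectamine minus untreated, and the difference of the first 2. The 2-sided F tests were adjusted by Benjamini-Hochberg over all genes tested, a gene was called at adjusted p 0.05, and the adjusted p-values of genes come from this model. The SE of a log2 fold change is its size divided by the square root of F. No replicate block was used, because the labels do not say that a number marks a shared mouse, culture or day. The deviations of replicate 1 from replicate 2 correlated between groups by -0.174 to 0.198 across 9550 genes. No clear pairing by number was seen, but with 1 deviation per group a shared mouse, culture or day cannot be excluded.

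Of 32 gene lists, 30 had at least 3 tested members and were tested with camera of limma 3.58.1, with a preset correlation of 0.01 between genes and Benjamini-Hochberg over the lists. They cover responses to LPS and DNA, stromal functions, stress and markers of other cell types. The lists of interferon genes and lymphocyte markers had too few members. Genes named in a comparison were those past the threshold with the largest changes (12 up and 8 down, or 10 each way for the difference, with a mean count of at least 50 in the higher group, both treated libraries on 1 side of both controls, and no predicted or clone symbols), up to 4 members with the smallest p per list, and 26 chosen genes. Only part of these are named, and exceptions are stated. The lists, the rule for names, the tests and the alternatives were chosen before the data were examined. Exceptions added afterwards were list tests on the difference, library size as the only scaling, lists for dsDNA against untreated cells and against LPS directly, gene families, the set of near-silent genes and the tests of explanations.

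A fold against a group with 0 counts in both libraries was computed against a floor of 3 counts per library. Floors cover counting error only. Positions come from GENCODE mouse release M21 on GRCm38, where 96.3% of the tested symbols had 1 position. Overlaps of called genes are given beside the number that independent lists would share.

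The model was tested on simulated data with the dispersions of these libraries, in 5 draws with 200 changed genes each. At a 2-fold change, 84.4% of changed genes were recovered with LPS, 84.4% with dsDNA, 83.6% with Lipofectamine and 75.6% for the difference, and at 1.25-fold 31.6%, 35.2%, 37.6% and 10.8%. Unchanged genes made up 5.96% to 6.98% of the calls. All groups were drawn with the same dispersion per gene, and only those 200 genes were changed per draw. Groups of unequal spread and changes in a large share of genes were not simulated, so the error rates of the real comparisons may be higher.

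The alternatives were DESeq2 1.42.0, DESeq2 size factors in edgeR, no filter beyond a count above 0, CPM above 1 in at least 2 libraries, a replicate block, the 4 libraries of a comparison alone, a log2 fold change of at least 1 in size, untreated cells as control of dsDNA, camera with an estimated correlation, fry, each library left out in turn, and library size as the only scaling. With 1 library left out, the lone library of a group was assumed to vary like the other groups. R 4.3.3, Python 3.11.15 and matplotlib 3.10.9 were used.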

Results

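RNA from 8 libraries of mouse adipose-tissue-derived mesenchymal stem cells (ASCs) was sequenced. ASCs are the plastic-adherent stromal cells grown from digested fat, here from the inguinal pad, and were used at passage 4. The libraries fell into 4 groups of 2. They were untreated cells, cells given lipopolysaccharide (LPS, a bacterial cell wall component) at 100 ng/ml, cells given the lipid transfection reagent Lipofectamine, and cells transfected with double-stranded DNA (dsDNA) at 400 ng/ml in that reagent. The labels give 4 h between treatment and collection for LPS and dsDNA, and no time for untreated and Lipofectamine cells. A difference in collection time between groups therefore cannot be told apart from a treatment effect. Total counts per library ran from 16301782 (LPS replicate 2) to 26418041 (untreated replicate 1), and 3 counts in a library stood for 0.106 to 0.188 on the counts-per-million scale (CPM). Of 24421 gene symbols, 14072 passed the low-count filter and held 99.97% of the counts. Counts varied between the replicates of a group more than sampling alone gives, by a chi-square per degree of freedom of 2.46 with Lipofectamine, 3.33 untreated, 3.74 with LPS and 9.29 with dsDNA. The labels do not say whether replicates were separate cultures or animals, so the p-values here measure the spread between samples, which may be technical. That spread was pooled over the 4 groups, though it was unequal. The p-values may therefore be too small for comparisons with dsDNA and too large for Lipofectamine against untreated cells. The RNA kit does not mark strand, so reads of overlapping and antisense genes cannot be told apart. Counts of close relatives (the Gbp, Ifit, Oas, Ifi200, H2, Mx and Saa families, Cxcl1 and Cxcl2) can be split between copies and are uncertain to that extent.

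**Figure D1:**
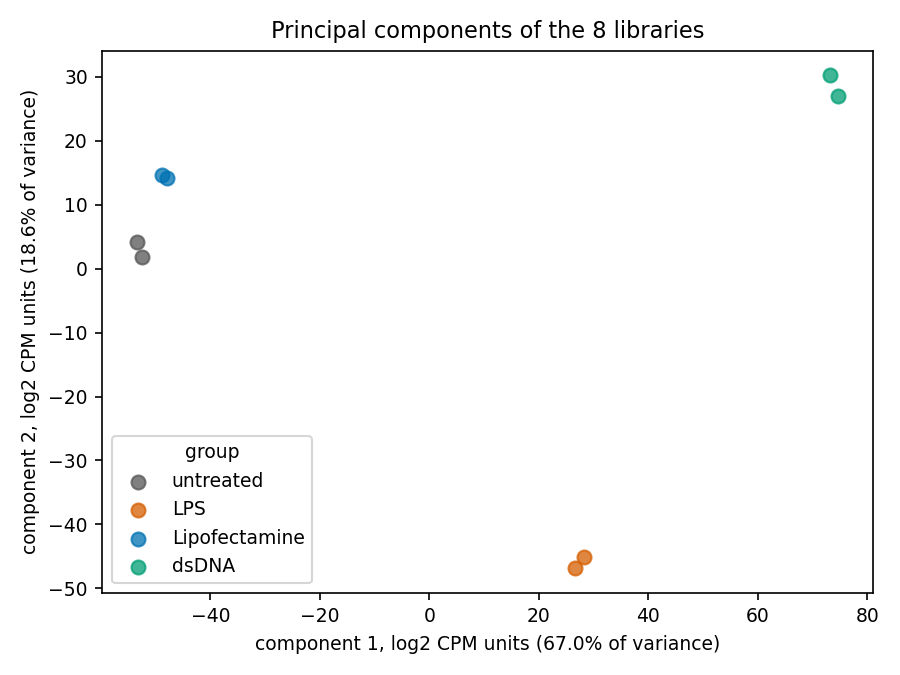
Principal components 1 and 2 (axes, in arbitrary units of log2 CPM) of the 14072 genes tested, 1 point per library. Component 1 holds 67.0% of the variance and component 2 holds 18.6%, and the 2 libraries of each group lie together.

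LPS against untreated cells showed what differed 4 h after LPS. The antiviral gene Rsad2 rose from 0.843 ± 0.297 to 942 ± 16.2 CPM (mean ± SD, n = 2), a log2 fold change of 10.13 ± 0.12 (SE, adjusted p = 6.04e-23). The T cell chemokine gene Cxcl10 rose by 9.28 ± 0.14 on the same scale, to 2148 ± 173 CPM. Il1b, which encodes interleukin-1 beta, rose from 0.146 ± 0.00683 to 149 ± 0.609 CPM (log2 fold change 9.95 ± 0.16). Il12b, the shared subunit of interleukins 12 and 23, had 0 counts in both untreated libraries and 2789 and 2217 counts with LPS, at least 1268-fold higher against a floor of 3 counts per library. On assembly GRCm38 these genes lie on chromosome 12 from 26442746 to 26456452 (Rsad2), chromosome 5 from 92346638 to 92348889 (Cxcl10), chromosome 2 from 129364570 to 129371139 (Il1b) and chromosome 11 from 44400063 to 44414033 (Il12b).

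Interferon-stimulated genes rose as a group with LPS. Of 43 measured, 42 were higher and none lower over all genes tested, and 43 were higher adjusted over the list alone, with a median log2 fold change of 4.90 (camera adjusted p = 0.00214 with an estimated correlation). Among them were Cmpk2, a nucleotide kinase (9.67 ± 0.11), Gbp5, a guanylate-binding protein (8.06 ± 0.11), Isg15, a ubiquitin-like modifier (5.25 ± 0.10), and Irf7, a transcription factor of the interferon response (4.55 ± 0.08). The interferon beta gene Ifnb1 had 5 and 2 counts with LPS against 0 in both untreated libraries, at least 1.70-fold higher. Its call (adjusted p = 0.0166) was lost without either untreated replicate (adjusted p = 0.0751 and 0.0669) and without LPS replicate 1 (0.126). Ifnb1 was the only tested member of the list of type I and III interferon genes, so that list had no test. Genes of cytosolic DNA sensing rose too (12 higher and 1 lower of 19, 12 and 2 adjusted over the list alone, median 1.24, adjusted p = 0.0138 with an estimated correlation, 11 and 3 under library size alone). They included Mb21d1, which encodes the DNA sensor cGAS (1.24 ± 0.11). For MHC class I antigen processing, 17 of 19 genes were higher and none lower (18 adjusted over the list alone, median 1.49, adjusted p = 0.00214 with an estimated correlation). The class I gene H2-Q4 rose by 3.71 ± 0.08, and Nlrc5, the transactivator of class I genes, by 5.02 ± 0.11.

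Inflammatory genes rose beside the interferon group. Cytokine genes were higher in 15 of 19 cases and lower in none (the same count adjusted over the list alone, median log2 fold change 3.60, camera adjusted p = 0.00821 with an estimated correlation). Il6, an acute phase cytokine, rose from 19.5 ± 1.27 to 341 ± 8.73 CPM (n = 2, log2 fold change 4.13 ± 0.10), and Il1a rose by 6.40 ± 0.17. Tnf rose by 6.01 ± 0.16, or by 6.61 without untreated replicate 1. Of 21 chemokine genes, 18 were higher and 1 lower by either adjustment (median 4.72, adjusted p = 0.00821 with an estimated correlation). The neutrophil chemokine genes Cxcl2 and Cxcl1 rose by 7.72 ± 0.12 and 5.37 ± 0.10, and the monocyte chemokine gene Ccl2 by 4.12 ± 0.07. All 13 acute phase and antimicrobial genes were higher by either adjustment (median 2.26, adjusted p = 0.00821 with an estimated correlation), among them Ptx3, a soluble pattern recognition protein (4.33 ± 0.08). NF-kB regulators were higher in 18 of 20 cases and lower in none by either adjustment (median 1.36, adjusted p = 0.00711 with an estimated correlation). The inhibitor genes Nfkbia and Tnfaip3 rose by 2.55 ± 0.07 and 3.37 ± 0.08. In the list of LPS recognition and Toll-like receptor signalling, 8 of 19 genes were higher and none lower by either adjustment (adjusted p = 0.0300 with an estimated correlation). The LPS co-receptor gene Cd14 rose by 2.60 ± 0.08, while Tlr4 itself stood at -0.12 ± 0.13 and was not called.

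Macrophage markers were present in these libraries and moved both ways with LPS. Of 16 markers, 14 stood at 10 CPM or more in untreated cells, 4 were higher and 7 lower with LPS (4 and 8 adjusted over the list alone), and the list was not called (median -0.23, adjusted p = 0.602). Adgre1, which encodes F4/80, rose by 0.97 ± 0.08 and Fcgr1, an Fc receptor gene, by 1.46 ± 0.15. Csf1r, the receptor of the macrophage growth factor, fell by 0.44 ± 0.06 and the mannose receptor gene Mrc1 by 0.81 ± 0.12, both named after their values were seen. No lymphocyte marker passed the count filter. Adhesion genes were higher in 9 of 13 cases and lower in 1 by either adjustment (median 0.54, adjusted p = 0.0116 with an estimated correlation). Icam1, a ligand for leukocyte integrins, rose by 2.36 ± 0.06. Immunomodulatory factors of mesenchymal stem cells were higher in 14 of 19 cases and lower in 1 by either adjustment (median 1.14, adjusted p = 0.00821 with an estimated correlation). They included Cd274, which encodes the checkpoint ligand PD-L1 (6.18 ± 0.10), and Ptgs2, the inducible prostaglandin synthase (1.34 ± 0.06).

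Lower with LPS were genes of cholesterol synthesis and of proliferation. Of 22 cholesterol genes, 19 were lower and none higher (20 adjusted over the list alone, median log2 fold change -0.54, camera adjusted p = 3.37e-05, adjusted p = 0.0866 with an estimated correlation). Hmgcs1, the synthase that feeds the pathway, fell by 0.73 ± 0.07. Of 24 proliferation genes, 11 were lower and none higher (13 lower and 1 higher adjusted over the list alone, median -0.20, adjusted p = 0.00974, adjusted p = 0.106 with an estimated correlation). The cyclin D1 gene Ccnd1 fell by 2.63 ± 0.08. Genes of glycolysis and hypoxia were higher in 9 of 15 cases and lower in 2 (10 and 2 adjusted over the list alone, adjusted p = 0.0127, adjusted p = 0.165 with an estimated correlation). Egln3, a hypoxia-induced prolyl hydroxylase gene, rose by 1.52 ± 0.08. For inflammasome, pyroptosis and necroptosis genes, 10 of 18 were higher and 2 lower (11 and 2 adjusted over the list alone, adjusted p = 5.63e-07, adjusted p = 0.0533 with an estimated correlation), among them the inflammasome gene Nlrp3 (2.91 ± 0.11) and Mlkl, the effector of necroptosis (2.11 ± 0.07). Outside any list, Fgd2, a guanine nucleotide exchange factor gene, stood at a log2 fold change of -3.03 ± 0.39.

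Of the 30 lists tested with LPS, 14 were called, 12 higher and 2 lower, and 10 of them were called with an estimated correlation. The rest held genes that went both ways or moved little, with adjusted p from 0.0848 to 0.886. Higher and lower members numbered 7 and 5 of 16 for mesenchymal stromal identity, 7 and 1 of 20 for extracellular matrix, 7 and 7 of 18 for matrix proteases, and 2 and 4 of 11 for adipogenic and mature adipocyte genes. They numbered 4 and 2 of 11 for osteogenic genes, 5 and 3 of 19 for the unfolded protein response, 6 and 0 of 11 for heat shock, 4 and 3 of 14 for p53 targets, and 6 and 1 of 12 for the NRF2 oxidative stress response. They numbered 1 and 3 of 16 for lysosome and autophagy, 9 and 6 of 16 for immediate early genes, 1 and 1 of 12 for endothelial markers, 1 and 5 of 11 for mural markers, 0 and 2 of 6 for epithelial markers and 0 and 1 of 5 for Schwann cell markers. Adjusted over the list alone, the counts were 8 and 6 for stromal identity, 7 and 0 for heat shock, 5 and 4 for p53 targets and 7 and 2 for NRF2, and the same for the others. The median and mean of the log2 fold changes differed in sign for macrophage markers (-0.23 and 0.01) and endothelial markers (0.05 and -0.05), whose tests pointed down. The endothelial median was -0.09 under library size alone. That scaling gave more lower than higher genes for stromal identity (5 higher and 6 lower), matrix (3 and 5), proteases (7 and 8), osteogenic (2 and 3), unfolded protein response (1 and 5), p53 (2 and 7) and endothelial genes (1 and 3). Pdgfra, a receptor gene of stromal cells, rose by 0.98 ± 0.05.

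In all, 4437 genes were called with LPS, 2442 higher and 1995 lower. Scaling by library size alone, chosen after seeing the data, lowered the median log2 fold change of all genes from -0.01 to -0.15 and gave 1694 higher and 4193 lower, so small falls depend on the scaling.

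**Figure D2:**
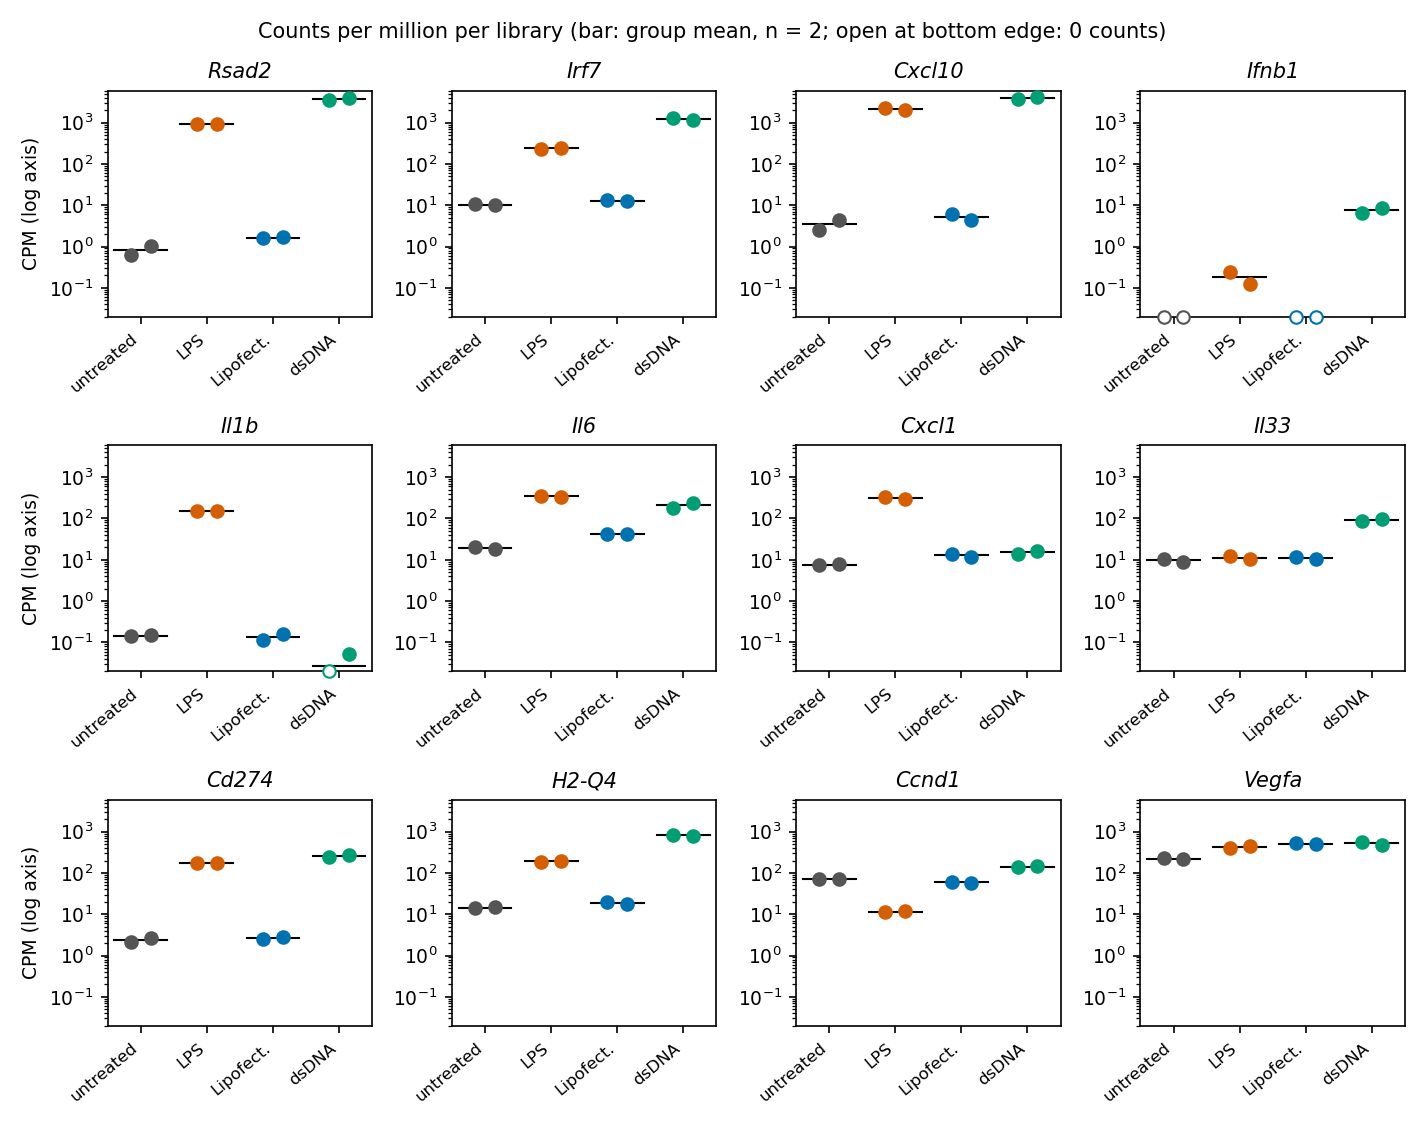
CPM (log axis) of 12 named genes in each of the 8 libraries, 1 point per library, with the bar at the group mean. Points at the bottom edge stand for 0 counts. Rsad2 lay at 942 CPM with LPS and 3734 CPM with dsDNA, and Il1b at 149 CPM with LPS and 0.0268 CPM with dsDNA.

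dsDNA against Lipofectamine showed what differed with the transfected DNA beyond the reagent. Ifnb1, the interferon beta gene, had 131 and 161 counts with dsDNA and 0 in both Lipofectamine libraries, at least 64.4-fold higher against a floor of 3 counts per library (adjusted p = 2.51e-10). Rsad2 rose from 1.64 ± 0.0616 to 3734 ± 408 CPM (mean ± SD, n = 2), a log2 fold change of 11.15 ± 0.11 (SE). The T cell chemokine gene Cxcl10 rose by 9.51 ± 0.13. Il1b had 1 count in 1 dsDNA library and 0 in the other, and was not called (adjusted p = 0.0987). Ifnb1 lies on chromosome 4 from 88522025 to 88522774 and the transactivator gene Nlrc5 on chromosome 8 from 94434356 to 94527272 on GRCm38.

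All 43 interferon-stimulated genes measured were higher with dsDNA by either adjustment (over all genes and adjusted over the list alone), with a median log2 fold change of 6.26 (camera adjusted p = 0.00245 with an estimated correlation). Cmpk2 rose by 11.24 ± 0.11, Irf7 by 6.56 ± 0.08, and Isg15 by 6.33 ± 0.10. Gbp10 and Cxcl11 had 0 counts in both Lipofectamine libraries and were at least 205-fold and 157-fold higher. Genes of MHC class I antigen processing were higher in 18 of 19 cases and lower in none by either adjustment (median 2.68, adjusted p = 0.00162 with an estimated correlation). H2-Q4 rose by 5.44 ± 0.08 and Nlrc5 by 6.76 ± 0.11. Cytosolic DNA sensing genes were higher in 12 of 19 cases and lower in 1 (12 and 2 adjusted over the list alone, median 1.32, adjusted p = 0.0349 with an estimated correlation), and under library size alone in 12 and 7. The sensor gene Mb21d1 rose by 2.14 ± 0.11, and Tmem173, which encodes its adaptor STING, by 1.18 ± 0.07. Samhd1, a dNTP hydrolase that restricts viruses, rose by 3.36 ± 0.06.

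Inflammatory lists were higher with dsDNA under the preset correlation and missed the threshold with an estimated one. The estimated correlation rests on the 4 residual degrees of freedom, so a missed threshold does not show that a list stayed unchanged. For cytokines, 14 of 19 genes were higher and none lower by either adjustment (median 1.49, or 1.13 with the gene at 0 counts set to its bound, camera adjusted p = 8.81e-05, adjusted p = 0.0858 with an estimated correlation). Il33, an alarmin cytokine, rose from 11.2 ± 1.08 to 92.3 ± 8.70 CPM (3.05 ± 0.10, n = 2), Il6 rose by 2.34 ± 0.09 and Tnf by 1.82 ± 0.23. For chemokines, 17 of 21 genes were higher and none lower by either adjustment (median 2.58, adjusted p = 5.34e-17, adjusted p = 0.0770 with an estimated correlation). Ccl5, a T cell and monocyte chemokine, rose by 8.59 ± 0.21 and Ccl2 by 3.86 ± 0.07. For NF-kB regulators, 16 of 20 were higher and none lower by either adjustment (median 0.95, adjusted p = 1.36e-07, adjusted p = 0.0505 with an estimated correlation), with Tnfaip3 at 2.36 ± 0.07. For acute phase genes, 12 of 13 were higher and none lower by either adjustment (adjusted p = 5.83e-10, adjusted p = 0.0640 with an estimated correlation), among them Cfb, complement factor B (4.13 ± 0.08). Of the LPS recognition list, 10 of 19 were higher and 2 lower (11 and 2 adjusted over the list alone, 8 and 5 under library size alone, adjusted p = 0.000350, adjusted p = 0.0770 with an estimated correlation). The receptor genes Tlr3 and Tlr2 rose by 5.91 ± 0.12 and 4.01 ± 0.08, and Cd14 fell by 0.79 ± 0.09. Of 16 macrophage markers, 9 were higher and 2 lower by either adjustment and the list was not called (median 0.23, adjusted p = 0.244), and under library size alone 4 were higher and 4 lower with a median of 0.00. Fcgr1 rose by 4.42 ± 0.13, while Lyz2, the macrophage lysozyme gene and the most abundant marker at 491 CPM with Lipofectamine, fell by 0.59 ± 0.06.

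Cell death, adhesion and immunomodulatory genes rose in part. Of 18 inflammasome, pyroptosis and necroptosis genes, 14 were higher and 1 lower by either adjustment (median log2 fold change 1.15, camera adjusted p = 7.47e-10, adjusted p = 0.0507 with an estimated correlation), with Mlkl at 3.40 ± 0.07 and Casp4, an inflammatory caspase gene, at 3.73 ± 0.10. Of 13 adhesion genes, 7 were higher and 2 lower (8 and 2 adjusted over the list alone, 5 and 3 under library size alone, adjusted p = 0.00264, adjusted p = 0.0770 with an estimated correlation), with Icam1 at 1.64 ± 0.06. Of 19 immunomodulatory factors, 11 were higher and 2 lower by either adjustment (adjusted p = 1.48e-05, adjusted p = 0.0505 with an estimated correlation). They included Cd274 (6.60 ± 0.10), the signalling inhibitor gene Socs1 (5.01 ± 0.14) and Lgals9, which encodes galectin-9 (3.48 ± 0.06). The median of that list was 0.22, and -0.01 under library size alone, where 7 were higher and 5 lower. Against untreated cells, chosen after seeing the data, it was 1.09, with 13 higher and 1 lower. Of the 19 factors, 8 had also risen with Lipofectamine alone (list median 0.29). Of 11 heat shock genes, 6 were higher and none lower by either adjustment (adjusted p = 0.00336, adjusted p = 0.0787 with an estimated correlation), with the chaperone gene Hspa1b at 2.22 ± 0.07. Under library size alone 5 heat shock genes were higher and 4 lower, and their median fell from 0.33 to 0.10.

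Cholesterol synthesis genes were lower in 21 of 22 cases and higher in none by either adjustment (median log2 fold change -0.65, camera adjusted p = 2.92e-05, adjusted p = 0.0902 with an estimated correlation). Sqle, squalene epoxidase, fell by 1.26 ± 0.08. Mural markers were lower in 8 of 11 cases and higher in none by either adjustment (median -0.35, adjusted p = 0.0415, adjusted p = 0.240 with an estimated correlation), with Cnn1, a smooth muscle calponin gene, at -0.95 ± 0.05. Proliferation genes were higher than with Lipofectamine in 14 of 24 cases and lower in none by either adjustment (median 0.21, or -0.02 with 8 higher and 4 lower under library size alone, adjusted p = 0.0494, adjusted p = 0.193 with an estimated correlation). The call of proliferation genes was lost without Lipofectamine replicate 1 (adjusted p = 0.0542), without dsDNA replicate 1 (0.0575) or 2 (0.113) and under library size alone (0.119), and that of mural markers without dsDNA replicate 2 (0.0531). Mcm6, a helicase subunit gene, rose by 1.61 ± 0.06 and Ccnd1 by 1.26 ± 0.07. Against untreated cells, a control added after seeing the data for the lists, 6 proliferation genes were higher and 8 lower (median -0.08, not called), and cholesterol genes stayed lower (1 higher and 14 lower, adjusted p = 0.00338). That control also called 3 lists that were not called against Lipofectamine, namely stromal identity (8 higher and 0 lower, adjusted p = 0.0262), the unfolded protein response (3 and 11, adjusted p = 0.0449) and immediate early genes (12 and 2, adjusted p = 0.0174). Outside any list, Hcn4, a pacemaker channel gene, fell by 3.39 ± 0.10 from 128 ± 14.2 CPM, while untreated cells held 24.4 ± 0.579 CPM.

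Lists not called with dsDNA held genes that went both ways or moved little, with adjusted p from 0.200 to 0.995. Higher and lower members numbered 6 and 5 of 16 for mesenchymal stromal identity, 7 and 5 of 20 for extracellular matrix, 8 and 7 of 18 for matrix proteases, 2 and 5 of 11 for adipogenic and 3 and 2 of 11 for osteogenic genes. They numbered 4 and 6 of 19 for the unfolded protein response, 8 and 4 of 14 for p53 targets, 3 and 4 of 12 for the NRF2 response, 4 and 3 of 16 for lysosome and autophagy, 9 and 4 of 16 for immediate early genes and 2 and 4 of 15 for glycolysis and hypoxia. They numbered 3 and 1 of 12 for endothelial, 0 and 2 of 6 for epithelial and 1 and 1 of 5 for Schwann cell markers. Adjusted over the list alone, only adipogenic (2 and 6) and immediate early genes (10 and 4) had other counts. For stromal identity the median log2 fold change (-0.01) lay below 0 and the mean (0.41) above it, and the test pointed up. For lysosome genes the median was 0.02 and the mean -0.03, and for matrix, proteases and endothelial markers the median and mean lay above 0 while the test pointed down. Under library size alone the medians of lysosome, matrix and protease genes lay below 0, and with DESeq2 size factors that of stromal identity lay above 0. Under library size alone more genes were lower than higher for stromal identity (5 higher and 8 lower), matrix (3 and 12), proteases (6 and 9), osteogenic (3 and 5), lysosome (1 and 9) and endothelial genes (2 and 3).

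In all, 7562 genes were called with dsDNA, 3687 higher and 3875 lower. Of the 30 lists, 15 were called, 13 higher and 2 lower, and 3 with an estimated correlation. Library size alone, chosen after seeing the data, moved the median of all genes from -0.04 to -0.27 and gave 2355 higher and 6734 lower.

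**Figure D3:**
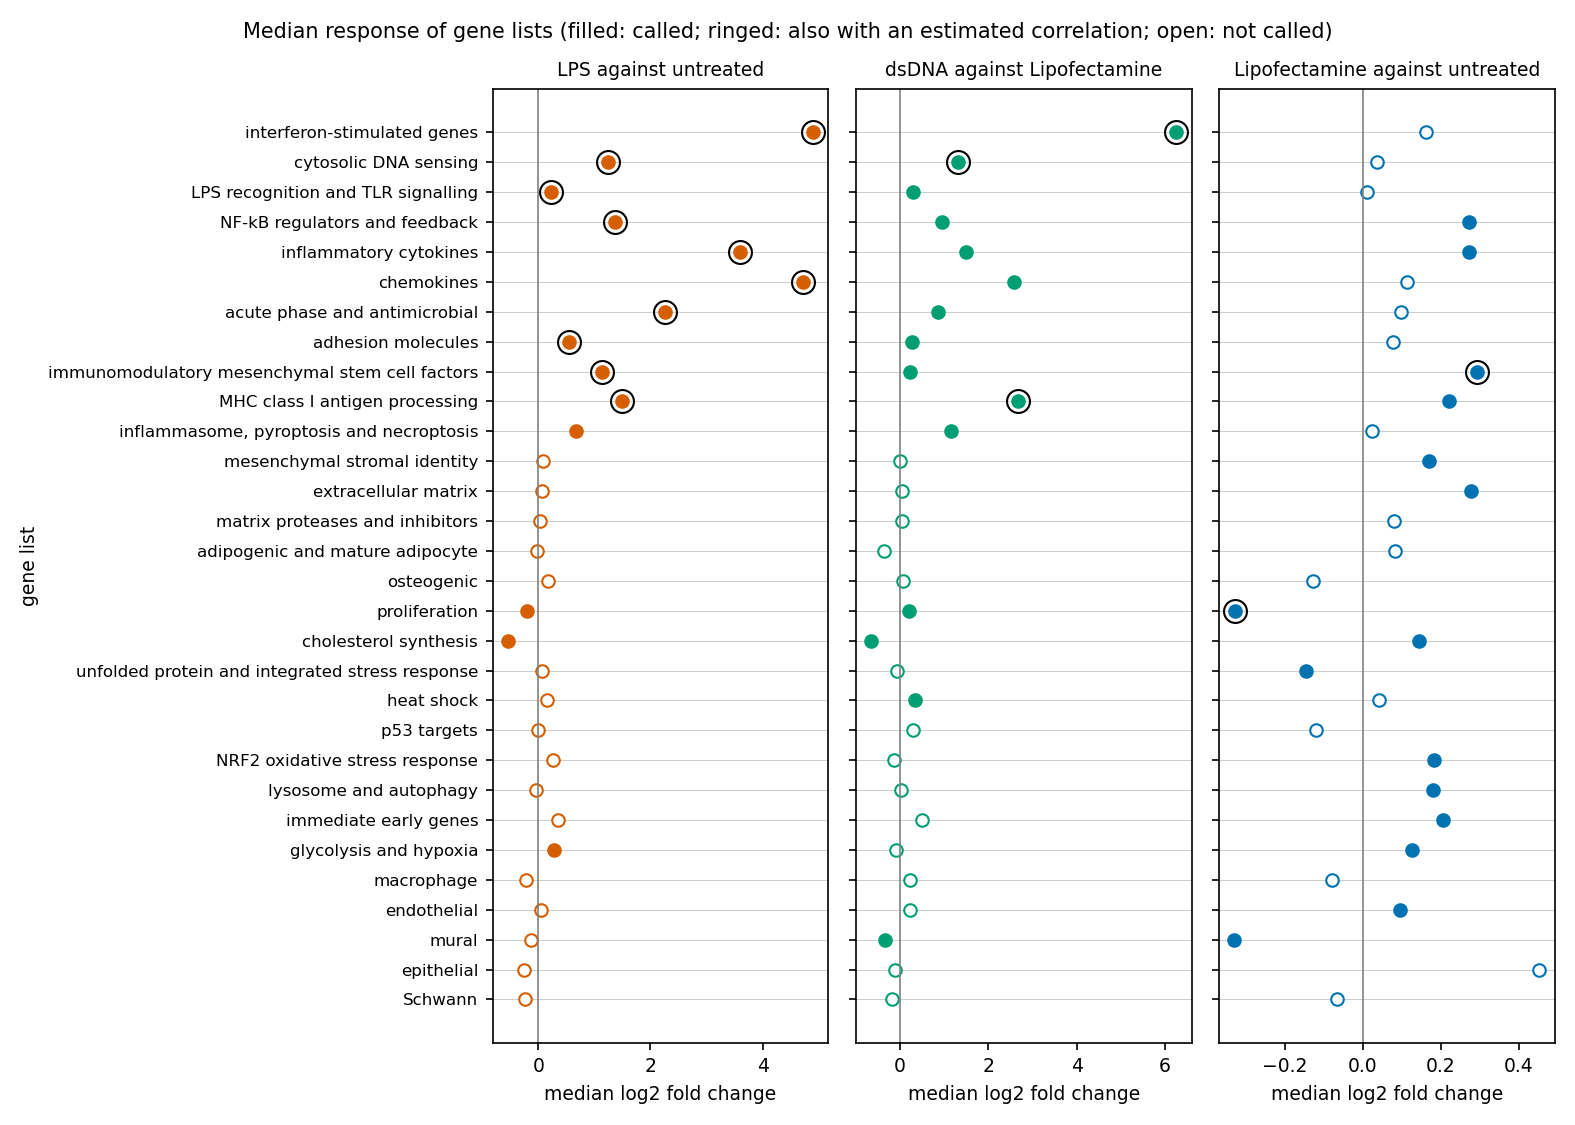
Median log2 fold change (x axis) of the tested members of 30 gene lists (y axis) in the 3 comparisons against a control, with a narrower x axis for Lipofectamine. Filled points are lists called by camera with the preset correlation, ringed points those called also with an estimated correlation, and open points those not called. Interferon-stimulated genes had the medians 4.90 with LPS, 6.26 with dsDNA and 0.16 with Lipofectamine, and the medians of 6 lists with LPS, 7 with dsDNA and 2 with Lipofectamine change sign with DESeq2 size factors or library size alone.

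Lipofectamine against untreated cells showed what differed with the reagent alone. Proliferation genes were lower in 17 of 24 cases and higher in none (19 lower adjusted over the list alone, median log2 fold change -0.33, camera adjusted p = 6.66e-10, adjusted p = 0.0473 with an estimated correlation). Top2a, a topoisomerase of dividing cells, fell by 0.50 ± 0.06 (SE, n = 2 per group) and Mcm3, a helicase subunit gene, by 0.51 ± 0.07. Immunomodulatory factors were higher in 8 of 19 cases and lower in none by either adjustment (median 0.29, adjusted p = 8.69e-09, adjusted p = 0.0473 with an estimated correlation). Vegfa, the vascular growth factor gene, rose from 222 ± 6.82 to 511 ± 9.78 CPM (1.20 ± 0.07), Ptgs2 by 1.05 ± 0.06 and Fgl2, a fibrinogen-like immunoregulator gene, by 1.69 ± 0.12. Serpinb2, which encodes a plasminogen activator inhibitor, rose from 6.24 ± 0.272 to 66.6 ± 6.99 CPM (3.41 ± 0.10), and lies on chromosome 1 from 107511423 to 107535478 on GRCm38. Adamts5, a gene of matrix cleavage, fell by 1.79 ± 0.06.

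Extracellular matrix genes were higher in 12 of 20 cases and lower in 3 with the reagent (13 and 3 adjusted over the list alone, median log2 fold change 0.28, camera adjusted p = 2.39e-06, adjusted p = 0.0807 with an estimated correlation), with the collagen VI genes Col6a2 and Col6a1 at 0.92 ± 0.06 and 0.78 ± 0.05. Mural markers were lower in 6 of 11 cases and higher in 1 by either adjustment (median -0.33, adjusted p = 6.23e-05, adjusted p = 0.114 with an estimated correlation). Acta2, smooth muscle actin, fell by 0.61 ± 0.04 and Myh11 by 0.87 ± 0.06, while Cspg4, a pericyte proteoglycan gene, rose by 1.26 ± 0.09. NF-kB regulators were higher in 12 of 20 cases and lower in 1 by either adjustment (adjusted p = 3.58e-05, adjusted p = 0.0807 with an estimated correlation), with Tnfaip2 at 0.92 ± 0.05. Glycolysis and hypoxia genes were higher in 7 of 15 cases by either adjustment (adjusted p = 1.02e-05, adjusted p = 0.0807 with an estimated correlation), with Bnip3, a mitophagy gene, at 0.74 ± 0.08. Immediate early genes were higher in 8 of 16 cases and lower in 1 by either adjustment (adjusted p = 0.194 with an estimated correlation), with Fosl1, an AP-1 subunit gene, at 1.60 ± 0.15. Cholesterol genes were higher in 8 of 22 cases and lower in 1 by either adjustment (median 0.14, adjusted p = 0.00277, adjusted p = 0.194 with an estimated correlation). Interferon-stimulated genes were higher in 9 of 43 cases and lower in 2 (10 and 2 adjusted over the list alone), and the list was not called (median 0.16, adjusted p = 0.103), but was called without untreated replicate 2 (adjusted p = 0.00100). Il6 rose by 1.07 ± 0.10 and Ccl2 by 0.57 ± 0.06, while Ifnb1 had 0 counts in all 4 libraries. Of 16 macrophage markers, 1 was higher and 3 lower by either adjustment, and the list was not called (adjusted p = 0.297).

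More lists changed with the reagent. Called higher with the preset correlation were stromal identity (4 higher and 0 lower of 16, 6 and 0 adjusted over the list alone, adjusted p = 0.00707 and, with an estimated correlation, adjusted p = 0.194), lysosome and autophagy (9 and 0 of 16 by either adjustment, 0.000700 and 0.253) and the NRF2 response (5 and 1 of 12, 6 and 1 over the list alone, 0.0146 and 0.194). So were MHC class I processing (7 and 1 of 19, 8 and 2 over the list alone, 0.0146 and 0.177), cytokines (3 and 1 of 19 by either adjustment, 0.0268 and 0.278) and endothelial markers (2 and 0 of 12 by either adjustment, 0.0268 and 0.278). The cytokine call was lost without untreated replicate 2 (adjusted p = 0.111) or Lipofectamine replicate 1 (0.0673), and the endothelial call without untreated replicate 2 (0.0592) or Lipofectamine replicate 2 (0.0542). The cytokine list had a median log2 fold change of 0.27, or 0.19 with the genes at 0 counts set to their bound. The unfolded protein response was called lower (2 and 7 of 19, 2 and 9 over the list alone, adjusted p = 0.00655 and, with an estimated correlation, adjusted p = 0.194), with Dnajb9, a chaperone gene of the endoplasmic reticulum, at -0.52 ± 0.08. Not called were DNA sensing (2 and 2 of 19, 4 and 2 over the list alone), LPS recognition (1 and 1 of 19), chemokines (6 and 1 of 21, 8 and 3 alone), acute phase (4 and 0 of 13, 4 and 2 alone, 2 and 2 under library size alone), adhesion (3 and 3 of 13, 4 and 4 alone) and inflammasome genes (0 and 0 of 18). Nor were proteases (7 and 4 of 18, 7 and 5 alone), adipogenic (4 and 3 of 11), osteogenic (2 and 2 of 11, 2 and 4 alone), heat shock (3 and 1 of 11) and p53 genes (1 and 5 of 14, 2 and 5 alone), or epithelial (2 and 0 of 6, 3 and 0 alone) and Schwann cell markers (1 and 0 of 5). Epithelial markers were called without Lipofectamine replicate 2 (adjusted p = 0.0385), with DESeq2 size factors (0.0488) and under library size alone (0.0448). The median and mean had opposite signs for chemokines (0.11 and -0.01), inflammasome genes (0.02 and -0.02) and proteases (0.08 and -0.05). The test pointed down for LPS recognition, with a median of 0.01, and up for Schwann cell markers, with a median of -0.07. Under library size alone the medians of inflammasome and LPS recognition genes lay below 0.

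In all, 3052 genes were called with Lipofectamine, 1772 higher and 1280 lower, and 232 of them changed at least 2-fold. Of the 30 lists, 15 were called, 12 higher and 3 lower, and 2 with an estimated correlation. Leaving out 1 library gave 1446 to 1965 genes, the lowest without Lipofectamine replicate 2 and the highest without untreated replicate 1. Library size alone gave 1501 higher and 1647 lower, against a median shift of all genes from 0.01 to -0.03.

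The difference of the responses, dsDNA minus LPS with each against its own control, was tested directly. The lists were tested on this difference only after the data had been seen. MHC class I antigen processing rose more with dsDNA in 16 of 19 genes and less in none (median log2 difference 1.26, adjusted p = 0.0107 with an estimated correlation), with B2m, the class I light chain, at 1.22 ± 0.08 and H2-K1 at 1.26 ± 0.08 (SE, n = 2 per group). NF-kB regulators rose less with dsDNA in 14 of 20 genes and more in 1 (median -0.66, adjusted p = 0.0438 with an estimated correlation), with Zc3h12a, an RNase that limits inflammation, at -1.95 ± 0.10. Part of the NF-kB difference came with the Lipofectamine control, in which 12 of the 20 lay above untreated cells. With dsDNA against LPS directly, a comparison added after seeing the data that has untreated cells as the control of both, 11 were lower and 2 higher (median -0.24, adjusted p = 0.000706, adjusted p = 0.108 with an estimated correlation), and 9 to 12 were lower with 1 library left out. Against untreated cells 15 were higher with dsDNA and none lower (median 1.30), beside a median of 1.36 with LPS. Proliferation genes stood higher in the dsDNA response in 18 of 24 cases and lower in none (median 0.48, adjusted p = 0.0314 with an estimated correlation). Ccnd1 differed by 3.89 ± 0.11, and lay at 71.7 ± 0.850 CPM untreated, 11.6 ± 0.644 with LPS, 59.5 ± 1.73 with Lipofectamine and 142 ± 5.51 with dsDNA. Part of the proliferation difference came with the Lipofectamine control, whose proliferation genes lay below those of untreated cells. Directly against LPS 10 were higher and 4 lower (median 0.17, adjusted p = 0.108 with an estimated correlation). Under library size alone 7 were higher and 5 lower (median 0.05).

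Interferon-stimulated genes rose more with dsDNA in 39 of 43 cases and less in none (median log2 difference 1.15, camera adjusted p = 1.30e-27, adjusted p = 0.0980 with an estimated correlation). Ifit2, an antiviral RNA-binding gene, differed by 3.93 ± 0.13 and Irf7 by 2.02 ± 0.11. Cytokines rose less with dsDNA in 8 of 19 cases and more in 3 (median -1.05, adjusted p = 0.00222, adjusted p = 0.154 with an estimated correlation). Il6 differed by -1.79 ± 0.13, Il1a by -5.27 ± 0.35 and Lif, a cytokine of the interleukin-6 family, by -2.05 ± 0.09, while Il33 went the other way (2.83 ± 0.16). Il6 had risen with Lipofectamine alone, and dsDNA against LPS directly gave -0.72 ± 0.08 for Il6, -4.57 ± 0.14 for Il1a and -1.42 ± 0.06 for Lif. Chemokines rose less in 12 of 21 cases and more in 3 (median -0.39, adjusted p = 4.69e-08, adjusted p = 0.154 with an estimated correlation), with the neutrophil chemokine genes Cxcl2 and Cxcl1 at -6.42 ± 0.41 and -5.11 ± 0.14, and Ccl5 at 3.20 ± 0.44. Acute phase genes rose less in 8 of 13 cases and more in 4 (adjusted p = 0.000238, adjusted p = 0.154 with an estimated correlation), with Saa3, a serum amyloid gene, at -1.52 ± 0.08. Cd14 differed by -3.39 ± 0.12 and the inflammasome gene Nlrp3 by -2.40 ± 0.18. Beside these groups, 8 of 16 macrophage markers stood higher in the dsDNA response and 2 lower (median 0.43, adjusted p = 0.00853, adjusted p = 0.154 with an estimated correlation). Adgre1 differed by -0.91 ± 0.11 and Fcgr1 by 2.96 ± 0.22. Glycolysis and hypoxia genes stood lower in 7 of 15 cases and higher in none (adjusted p = 3.43e-05, adjusted p = 0.0980 with an estimated correlation), with Egln3 at -2.66 ± 0.12. The counts of these members were the same adjusted over the list alone, except 2 and 15 for NF-kB regulators and 4 and 12 for chemokines.

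More lists differed between the responses. Larger with dsDNA were DNA sensing (10 larger and 1 smaller of 19, adjusted p = 9.99e-05 and, with an estimated correlation, adjusted p = 0.154), inflammasome genes (11 and 1 of 18, 0.000675 and 0.154) and heat shock (5 and 1 of 11, 0.00327 and 0.137), each with the same counts adjusted over the list alone. Smaller were immunomodulatory factors (3 and 10 of 19, 4 and 11 over the list alone, 0.0355 and 0.154), the NRF2 response (1 and 4 of 12, 1 and 6 alone, 0.00336 and 0.154) and the unfolded protein response (2 and 7 of 19 by either adjustment, 0.0359 and 0.196). Immunomodulatory factors were not called without untreated replicate 1 (adjusted p = 0.0601) or LPS replicate 1 (0.0535), nor the unfolded protein response without untreated replicate 1 (0.0506), LPS replicate 2 (0.0522) or dsDNA replicate 2 (0.0546). Lgals9, which encodes galectin-9, stood at 1.99 ± 0.08 and Ptgs2 at -1.19 ± 0.09. Ptgs2 and the immunomodulatory list had risen with Lipofectamine alone, and against untreated cells Ptgs2 stood at 1.20 ± 0.06 with dsDNA and 1.34 ± 0.06 with LPS, which did not differ directly (-0.14 ± 0.06, adjusted p = 0.0625). For the list the medians against untreated cells were 1.09 with dsDNA and 1.14 with LPS, and directly 8 genes were higher and 7 lower (median 0.09, or -0.03 without LPS replicate 2 and under library size alone, where 8 were higher and 9 lower, adjusted p = 0.355). Not called were LPS recognition (7 and 5 of 19, median 0.04, or -0.04 under library size alone, and mean -0.13), adhesion (2 and 6 of 13), stromal identity (5 and 4 of 16), matrix (3 and 7 of 20, 3 and 8 alone), proteases (4 and 6 of 18, 4 and 9 alone), adipogenic (2 and 4 of 11, 2 and 6 alone) and osteogenic genes (1 and 3 of 11). Nor were cholesterol synthesis (1 and 6 of 22), p53 (8 and 3 of 14), lysosome (3 and 1 of 16, 1 and 4 under library size alone) and immediate early genes (8 and 2 of 16), or endothelial (2 and 1 of 12), mural (0 and 2 of 11), epithelial (0 and 1 of 6) and Schwann cell markers (1 and 0 of 5). Of these, adipogenic genes were called without dsDNA replicate 1 (adjusted p = 0.0430), p53 targets without dsDNA replicate 1 (0.00891) or 2 (0.0357), and immediate early genes without dsDNA replicate 2 (0.0132).

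In all, 4809 genes differed between the responses, 2395 higher and 2414 lower, and 1245 at least 2-fold. Library size alone gave 1946 higher and 3200 lower, with the median of all genes moved from -0.02 to -0.11. Of the 30 lists, 15 were called, 7 higher and 8 lower, and 3 with an estimated correlation. With dsDNA against LPS directly 4 of these 15 were not called, namely immunomodulatory factors (8 higher and 7 lower), the NRF2 response (3 and 6, adjusted p = 0.110), glycolysis and hypoxia (2 and 6, 0.106) and macrophage markers (9 and 4, 0.0566, or 0.0354 without LPS replicate 1). Called only directly were stromal identity (7 and 1, adjusted p = 0.0276, or 0.0640 without LPS replicate 2), immediate early genes (10 and 2, 0.00118) and mural markers (1 and 6, 0.000706). With an estimated correlation none of these 3 lists was called (adjusted p = 0.195, 0.195 and 0.108). The direct comparison called 3649 genes higher and 3397 lower.

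The LPS and dsDNA responses overlapped. Of the genes tested, 1646 were higher in both, where independent lists would share 640, and 1199 were lower in both, against 549. Another 201 were higher with LPS and lower with dsDNA, against 672, and 205 the reverse, against 523. Of the 2845 genes that changed in the same direction, 1039 changed more with dsDNA by the test of the difference, 223 more with LPS, and 1583 were not called different. The log2 fold changes correlated across genes with r = 0.69 and rho = 0.49, and with r = 0.86 and rho = 0.82 over the 3251 genes called in both. Genes are not independent replicates, so no p-value goes with these, and both responses include the spread of their own controls.

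**Figure D4:**
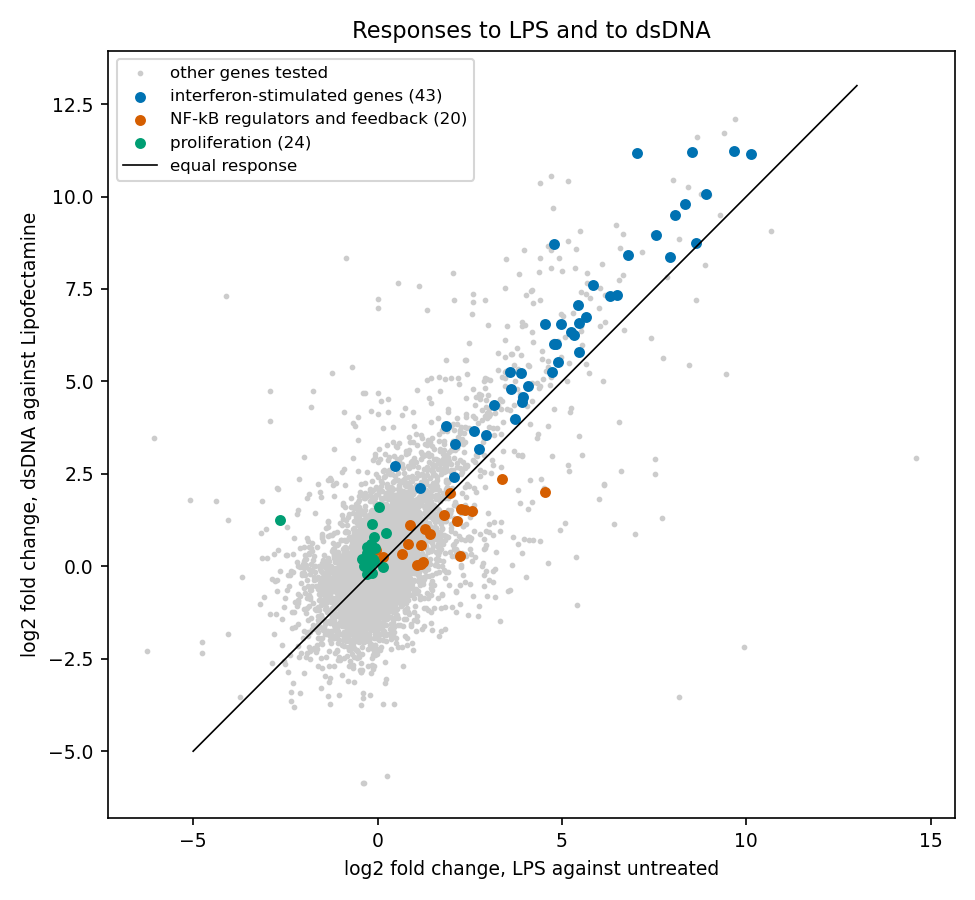
Log2 fold change with LPS against untreated (x axis) and with dsDNA against Lipofectamine (y axis) of each gene tested, with the genes of 3 lists in colour and the line of equal response. Genes with 0 counts in a control group are drawn at their fitted value, which is no bound. Interferon-stimulated genes lie mostly above the line (39 of 43 larger with dsDNA) and NF-kB regulators below it (14 of 20 smaller).

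The authors deposited tables of genes at adjusted p 0.05 and a log2 fold change of at least 1 in size. Their LPS table held 982 genes, of which 969 were called here by the same thresholds in the same direction, and 163 genes were called here and absent from that table. Their dsDNA table held 1908 genes, of which 1838 were called here in the same direction, and 262 were called here and absent there.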

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

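Library size as the only scaling, and all list tests on the difference of the responses, were chosen only after the results were seen. The counts of called genes stayed within 1.5 times those reported with DESeq2, DESeq2 size factors, no low-count filter, CPM above 1 in at least 2 libraries, a replicate block and library size alone (3600 to 5887 with LPS, 6458 to 9089 with dsDNA, 2207 to 3360 with Lipofectamine, 3829 to 5146 for the difference). Untreated cells as the control of dsDNA gave 8352 genes. A log2 fold change of at least 1 in size left 1132 genes with LPS, 2100 with dsDNA, 232 with Lipofectamine and 1245 for the difference, and 673 shared in the same direction and 23 in the opposite one, since most changes were smaller. Only the 4 libraries of the comparison gave 4633 genes with Lipofectamine (3052 with all libraries), 4991 with LPS (4437) and 7113 with dsDNA (7562). More genes without the dsDNA libraries and fewer with them is the direction that pooling the unequal spread would give. The cause was not tested. Leaving out 1 library gave 1446 (without Lipofectamine replicate 2) to 1965 genes (without untreated replicate 1) with Lipofectamine, with fewer samples in the test, 3317 to 3429 with LPS, 6225 to 7317 with dsDNA and 3777 to 5099 for the difference. An estimated correlation left 3 lists called with dsDNA, 2 with Lipofectamine and 3 for the difference, and fry, which does not compare a list with other genes, called 26 with dsDNA and 23 for the difference. With the estimated correlation 41 of 120 list results lost their call, and with fry 30 gained one. The correlation of the responses (r = 0.692) was 0.730 with CPM above 1 in at least 2 libraries and 0.635 (without LPS replicate 1) to 0.680 (without Lipofectamine replicate 2) with 1 library left out. These moves exceeded the SD of 0.0117 over 16 choices of 1 library per group, and the cause was not tested. Named genes that were called kept their direction and call under DESeq2, DESeq2 size factors, the replicate block and library size alone, and with 1 library left out only Ifnb1 with LPS lost its call (adjusted p from 0.0669 to 0.126). The depth limits small changes and genes of few counts, as 3 counts stand for 0.106 to 0.188 CPM.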

Other observations

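The tests of families, of lists on the difference of the responses, of near-silent genes and of explanations were chosen only after the result was seen, unlike the calls of single genes. The genes named in it, apart from Ifnb1, were chosen after their values were seen.

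Interferon alpha genes had too few counts to be tested. Ifna4 had 6 and 12 counts in the dsDNA libraries, Ifna5 had 6 and 8, and Ifna2 had 1 and 1, against 0 in the other 6 libraries. Ifne had 1 count in LPS replicate 2 and 0 elsewhere. Ifna1, Ifna6, Ifnk, Ifnl2 and Ifnl3 had 0 counts in all 8 libraries.

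Genes that share a symbol stem were tested as 333 families of at least 6 genes with camera, and the preset correlation called 17 families with LPS, 19 with dsDNA, 12 with Lipofectamine and 16 for the difference. With an estimated correlation 0 were called in each. That setting rests on the 4 residual degrees of freedom and could hardly call any family. Even the Ifit genes with dsDNA, 6 of 6 higher with a median log2 fold change of 9.26, had an adjusted p of 0.123. The families are therefore given as descriptions. A shared stem can take in genes outside the protein family named, so the counts are of symbols with that stem. The signs of the medians given here held under TMM, DESeq2 size factors and library size alone, except where stated. Galectin genes were higher with dsDNA in 4 of 6 cases (median log2 fold change 1.26, adjusted p = 3.67e-07), with Lgals8, a sensor of damaged vesicles, at 2.05 ± 0.07. Toll-like receptor genes were higher with dsDNA in 8 of 10 cases and lower in 1 (median 0.93, adjusted p = 4.13e-05), and the response exceeded that to LPS in 6 (median 0.98, adjusted p = 0.000404), with Tlr7 at 1.18 ± 0.26. Apolipoprotein L genes were higher in 6 of 7 cases with LPS (median 3.88, adjusted p = 1.68e-09) and in 7 of 7 with dsDNA (median 4.97, adjusted p = 3.53e-16).

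Genes of the HoxC cluster were lower with LPS in 5 of 7 cases and higher in none (median log2 fold change -0.49, adjusted p = 0.278, not called). The difference of the responses was positive in 5 and negative in none (median 0.63, adjusted p = 0.0341). Part of this came with the control, as 3 HoxC genes were lower and none higher with Lipofectamine (median -0.28), and 1 was higher and 3 lower with dsDNA against untreated cells (median -0.23, or -0.50 under library size alone). Hoxc8 fell by 0.59 ± 0.06 with LPS and differed by 0.63 ± 0.09, and Hoxc9 differed by 1.60 ± 0.15. Collagen genes were higher with Lipofectamine in 16 of 35 cases and lower in 5 (median 0.33, adjusted p = 0.000227). Genes with the Mcm stem were lower with Lipofectamine in 8 of 10 cases and higher in none (median -0.44, adjusted p = 0.000115). Their difference between the responses was positive in 8 (median 0.71, adjusted p = 3.18e-05), with Mcm10 at 1.67 ± 0.15. With dsDNA against untreated cells 3 were higher and 2 lower (median 0.01, or -0.25 under library size alone), so the contrast with Lipofectamine includes the fall in that control.

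Of 19 inflammatory cytokine genes 8 responded less to dsDNA than to LPS and 3 more, and of 21 chemokine genes 12 and 3, but neither list was called with an estimated correlation (adjusted p = 0.154 for each), and with dsDNA against LPS directly 10 cytokine genes were lower and 6 higher, and 12 chemokine genes lower and 8 higher. More macrophages in the LPS libraries would raise the macrophage markers together, but 7 of 16 were lower with LPS and 4 higher. The median of the markers was -0.23, against 3.60 for cytokine genes and 4.72 for chemokine genes, and Lyz2, the most abundant marker, had 526 ± 25.3 CPM untreated and 478 ± 13.5 with LPS (n = 2). Macrophages present in every library may still be the cells that responded to LPS, since 14 of the 16 markers stood at 10 CPM or more in untreated cells. Which cells made the cytokine RNA cannot be told apart in bulk RNA, and a fall of marker genes within macrophages given LPS was not tested.

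Interferon-stimulated genes rose more with dsDNA than with LPS in 39 of 43 cases, each response against its own control. On that difference the list was not called with an estimated correlation (adjusted p = 0.0980). With dsDNA against LPS directly 43 stood higher, and the list was called with an estimated correlation (adjusted p = 0.0269). Endotoxin in the transfected DNA as the whole cause would raise NF-kB regulators alongside, and 15 of 20 were higher and none lower with dsDNA against untreated cells. With dsDNA against LPS directly 11 of the 20 were lower and 2 higher. That majority was not held with 1 library left out, so this count cannot decide. The 14 that responded less with each response against its own control include the rise with Lipofectamine. Directly against LPS, cytokine genes were lower in 10 of 19 cases and higher in 6 (median -0.72, or -0.54 to -0.92 with 1 library left out). Acute phase genes were lower in 8 of 13 and higher in 5 (median -0.60, or -0.53 to -0.59). For the lower genes this argues against endotoxin as the whole cause, though neither list was called with an estimated correlation (adjusted p = 0.106 and 0.159). Endotoxin as a part of the cause stays open. Library size alone moved the median difference only from 1.15 to 1.06, and 38 of 43 genes kept a larger response. This argues against the choice between these 2 scalings as the cause. A change in total RNA per cell was not tested. Ifnb1 had 131 and 161 counts with dsDNA and 5 and 2 with LPS. With 0 counts in both controls the test of its difference between the responses was not called. With dsDNA against LPS directly it was called higher (log2 fold change 5.26 ± 0.42, adjusted p = 7.66e-09). Whether interferon, dose or uptake of the DNA accounts for the pattern was not tested.

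Among tested genes below 0.5 CPM with Lipofectamine, 223 rose at least 4-fold with dsDNA and 115 of these were higher with LPS, which is no share of all near-silent genes, since the count filter reads the treated groups too. Reads running on from a raised gene could add counts to such genes from either strand, and 28.3% of the 223 had a raised gene that overlapped them or was transcribed towards them within 50 kb, against 9.18% of 490 such genes not called higher (2-sided Fisher's exact test, p = 3.79e-10). Genes are not independent replicates, and raised genes close together can be each other's neighbours, so that p-value may be too small. A raised gene in any orientation within 50 kb was also more common (38.1% against 14.1%), so the excess is not particular to run-on. For the 28.3% run-on remains open, but it was not found for most. Mouse DNA of the whole genome in the transfection would give counts to genes that are otherwise silent. Of 6642 genes with 0 counts in the untreated and LPS libraries, 4.83% had a count with dsDNA and 4.28% with Lipofectamine. These are means of 2 libraries, with a ratio of 1.13. By library the values were 5.25% and 4.41% with dsDNA and 4.11% and 4.44% with Lipofectamine. The dsDNA libraries were shallower (22374824 and 20517908 counts against 24384161 and 23733644 with Lipofectamine), and the percentages were not corrected for depth. This comparison therefore cannot decide on DNA of the whole genome, and DNA of single genes stays open too. Dll1, a Notch ligand gene, rose from 0.0989 to 25.0 CPM with no raised gene within that distance. That the rest are genes switched on by the response to DNA is a hypothesis, and reads shared between related genes were not tested.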
